A study of Mus musculus with 14 samples.

How the data were processed

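The series holds 14 samples, of which 8 are droplet single-cell RNA libraries of sorted mouse thymic epithelial cells and 6 are chromatin accessibility (ATAC) samples of another strain, which were not analysed here. Groups were taken from the titles and genotypes in the labels: control and AireKO (genotypes Aire+/+ and Aire−/−) form the knockout experiment, and WT and 3xAireKI (Aire+/+ and homozygous for the knock-in allele) the knock-in experiment, with 2 libraries per group. Per the labels' protocols, the knock-in experiment used the v2 kit of the 10x 3′ chemistry, whereas for the knockout experiment a mixture of v2 and v3 kits is named without saying which library used which. The matrices list 737280 barcodes per library in the first and 6794880 in the second, so the 2 experiments differ in barcode set, and each genotype was compared only with the Aire-sufficient libraries of its own experiment.

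The values are raw counts of unique molecular identifiers per gene and barcode, as deposited, with no filter on cells. Per the submitters' processing notes, reads were processed with bcl2fastq and Cell Ranger 3.0.0 on mm10, while the file headers name software version 3.1.0. The annotation behind the counts is not given in the sources used here. Each matrix holds 31053 genes, and 35 symbols stand for 2 or more gene identifiers, which were kept apart. Gene positions were looked up by Ensembl identifier in the GENCODE annotation of mm10. Of the genes tested in the main class, 19816 had a position and 23 had none.

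A barcode was called a cell when its count reached 10% of the 99th percentile of the top 3000 barcodes of its library, with a floor of 500 UMIs. The resulting thresholds lay between 2476.7 (WT 2) and 4093 UMIs (control 1). Cells with fewer than 500 genes or more than 15% mitochondrial UMIs were removed. Scrublet (scanpy 1.11.5) scored doublets, and the top 0.8% per 1000 cells, 2.45% to 6.26% of a library, were removed. Free RNA was measured in the barcodes ranked 15000 to 50000, whose median was 402 UMIs in WT 1 and 40 to 103 UMIs in the other libraries. The level it would bring to a class is the number of cells times the mean count per such barcode, over the class UMIs. It made up 2.94% of the UMIs of the main class in WT 1, 2.29% in WT 2 and 0.353% to 1.08% in the others.

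The cells of each experiment were clustered together (2000 variable genes, 30 principal components, 20 shared nearest neighbours, Leiden with leidenalg 0.10.2 at resolution 1.5). Aire and the genes called between genotypes over all kept cells were left out. The called genes were 3122 higher and 5597 lower in the knockout, and 45 and 39 in the knock-in experiment. The numbers of clusters were 30 and 25. Clustering used no batch correction. Marker lists were fixed before the data were examined, and the rule that scores them was set after the clusters had been seen. A cluster took the list with the highest mean relative detection, at least 0.5, with at least 3 markers seen in 25% or more of its cells. It stayed unnamed when more than 50% of its cells scored as doublets, a limit added after 1 such cluster was seen, or when its 10 leading genes by fold, among genes seen in 25% or more of its cells, held more markers of another list than of its own. Lower resolutions, other scoring rules and other detection limits for leading genes were looked at while the rule was set. Leading genes were taken against the cells outside the class. This reference was chosen after cluster names and class shares had been seen under both references and before any class-level gene test, since against all other cells cluster 1 of the knock-in experiment, which holds much of the Aire signal, left the class through 1 gene (Apoa4). The chosen reference has the same weakness in the knockout experiment. It left clusters 5 and 15, mature against all other cells, unnamed through 1 myeloid marker each. They held 9.14% and 3.73% of AireKO 1 and 10.4% and 2.27% of AireKO 2 cells. Cluster 0, which scored highest for the mature list, was unnamed under both references, through 1 myeloid or 1 cortical marker. It held 15.1% and 16.2% of AireKO and 1.035% and 1.167% of control cells. The version with leading genes against all other cells and a version with no check of leading genes were run as alternatives. The check kept 13.9% and 16.7% of control cells, 37.6% and 37.0% of AireKO cells and 1.20% to 1.84% of WT and 3xAireKI cells out of the mature class. It kept 5.56% and 6.93% of control, 4.89% and 4.81% of AireKO, 6.06% and 14.8% of WT, and 5.39% and 5.18% of 3xAireKI cells out of the immature class.

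Raw counts were summed per library over the cells of a class, since cells are not replicates. The sums of the 8 libraries were tested in one fit with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, group as the only term), with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. The common dispersion was 0.031 with 5.519 prior degrees of freedom. The contrasts were AireKO against control, 3xAireKI against WT, and the difference of these. Other classes were tested likewise where each library of the comparison had at least 30 cells. Levels are CPM, UMI counts scaled to a common total with TMM-scaled library sizes. Where a gene had no UMI in a group, its fold was bounded with 3 counts per library.

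The named genes follow a rule fixed before the data were examined. Aire comes first. Then come the 10 largest rises and 10 largest falls among genes past the threshold, with both libraries of one group above both of the other and at least 10 CPM in the higher group. Up to 4 members of each fixed list with the lowest p, or up to 2 of the highest level where no member passed, complete them. Genes with Gm-number or Rik symbols were skipped when naming the largest rises and falls. Other symbols of that kind, such as AC132444.6 and AL589670.1, were kept. Genes named outside this rule are said to be chosen after their values were seen. The results of some genes are not reported here, and the totals over named genes in the sensitivity section still count them.

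The 34 fixed gene lists with at least 5 measured members were tested with fry (limma 3.58.1) on voom values, which asks whether a list moves one way on balance, and with camera at an estimated correlation, which sets a list against the other genes. Both were adjusted over the lists. The genes that fell and the genes that rose in AireKO were tested as sets in 3xAireKI in the same way, adjusted over the pair, and within clusters, adjusted over the clusters and sets. Because voom gives each gene its own weights, fry and camera p-values shift with the order of the group columns in the model. This was noticed when a change of sorting moved list calls. The alphabetical order was then fixed for all printed values, and the 24 orders were run for the main class. Between 25 and 28 lists passed by fry in AireKO and between 14 and 16 in 3xAireKI, and 0 lists passed by camera in any order.

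For per-cell measures each cell was thinned to 3000 UMIs, or 1500 in an alternative. Differences between 2 and 2 libraries in shares and per-cell measures were compared by exact two-sided permutation tests, whose smallest p is 0.333. Shares carry exact 95% binomial intervals, and a count of 0 allows up to 3 counts. These intervals and limits cover counting error only.

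Replicates were compared before use. Their counts differed by 12.2 to 26.2 times the sampling noise (chi-square over degrees of freedom), and 0 pairs were identical. The labels number the libraries of each experiment by batch, so libraries of one number share a batch. Deviations of same-numbered libraries from their group means correlated across genes with r = 0.169 (8909 genes with at least 10 CPM) in the knockout and r = 0.354 (8484 genes) in the knock-in experiment. The fit without the batch as a block is the main one, as fixed beforehand, and the blocked value is given where it changes a call.

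The tests were tried on simulated counts with 200 changed genes in each comparison among 19507 tested. For the AireKO design edgeR recovered 14.9% of 1.5-fold, 46.3% of 2-fold and 84.8% of 4-fold changes, with 8 false calls among 105. For the 3xAireKI design it recovered 17.9%, 47.8% and 80.3%, with 7 false calls among 104. Of 100 lists of unchanged genes, fry gave 3 (AireKO design) and 5 (3xAireKI design) an unadjusted p under 0.05. In the simulation as many genes rose as fell, genes with few counts were not changed, and genes were drawn independently. Its dispersion followed the trend with expression level alone, and no batch effect shared by same-numbered libraries was drawn. In the data 8463 genes were called in AireKO, 6020 of them lower, and members of a list may correlate. The simulation does not show how the tests do in that setting.

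Alternatives fixed beforehand were DESeq2 1.42.0, scaling by library size, no filter on low counts, the block, the 4 libraries of a comparison alone, each library left out, cells with at least 2 times the UMI threshold, a mitochondrial limit of 5%, doublets kept, a clustering that left out only Aire, all kept cells, sums thinned to the lowest total, the 200 largest falls, and camera. Chosen after seeing the data were the 2 versions of the check of leading genes, the subtraction of free RNA, and the same mix of clusters in every library. For the last, the profile of each cluster with at least 20 cells in every library of an experiment was weighted by its mean share of the class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.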

Results

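Aire is a transcriptional regulator of medullary thymic epithelial cells (mTECs), the cells that display proteins of other tissues to developing T cells. The samples set mice without Aire (AireKO) against Aire-sufficient controls, and mice homozygous for an Aire knock-in allele (3xAireKI) against wild-type mice (WT). Droplet single-cell RNA sequencing (10x Genomics 3′ counting with unique molecular identifiers, UMIs) was deposited for thymic epithelial cells of C57BL/6 mice at 8 weeks of age. There were 2 libraries each of control, AireKO, WT and 3xAireKI, numbered 1 and 2 by batch. The labels describe a sort of CD45-negative, EpCAM-positive cells, whereas the design text of the series speaks of mTEChigh cells from 1 mouse, so it is open how many animals stand behind a group. The p-values therefore measure only the spread between these libraries, which may be technical. Libraries held between 55934728 UMIs (WT 1) and 82073861 UMIs (AireKO 1), and 2985 to 7340 cells per library remained after filtering. Their median was 6145 to 10850 UMIs. WT 1 stood apart in free RNA. Before doublets were removed, 55.15% of its UMIs lay in the cells that passed the other filters, against 76.8% to 89.6% in the other libraries. Both WT libraries had more free RNA than both 3xAireKI libraries, so in that comparison free RNA went with the genotype. The mean free UMIs per barcode were 397 and 218 in WT, against 41.9 and 52.3 in 3xAireKI.

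Cells were named from marker genes fixed before the data were examined. Mature mTEC-like cells, named by Cd80, Cd52, Il2rg, MHC class II genes and others but not by Aire, are the main class of both comparisons, with 675 to 2195 cells and 9139877 to 25369388 UMIs per library. Different clusters held most of this class in the groups. Cluster 1 of the knockout experiment held 65.5% and 60.45% of the class in the control libraries, and 2.72% and 1.87% in AireKO, where clusters 4, 6, 7 and 10 held most of it. In the knock-in experiment cluster 1 held 47.9% and 57.9% of the class in WT, against 20.6% and 32.6% in 3xAireKI, where cluster 0 was the largest with 54.4% and 44.1%.

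Aire itself (ENSMUSG00000000731; chromosome 10, 78030022 to 78043610, minus strand, in mm10) was the first gene examined. Its level in mature mTEC-like cells was 718 ± 94.0 CPM (UMI counts scaled to a common library total; SD, n = 2) in control and 11.05 ± 1.29 CPM in AireKO, a log2 fold change of −6.02 (SE 0.18; adjusted p = 1.44e-07, edgeR). In WT it was 628 ± 58.6 CPM and in 3xAireKI 153 ± 3.05 CPM (log2 fold change −2.04, SE 0.15; adjusted p = 0.000567, edgeR). The UMIs behind these levels were 18064 and 11825 in control, 278 and 173 in AireKO, 5572 and 10991 in WT, and 3212 and 2865 in 3xAireKI. After each cell was thinned to 3000 UMIs, 70.1% of control and 2.48% of AireKO cells of the class had an Aire UMI, as did 65.5% of WT and 31.6% of 3xAireKI cells. Without thinning the shares were 90.0% and 85.4% in control, 6.82% and 5.15% in AireKO, 80.1% and 81.9% in WT, and 60.4% and 56.0% in 3xAireKI. Tuft-like cells, a type that should lack Aire, had an Aire UMI in 5.56% and 2.84% of thinned cells in control, 2.99% and 4.46% in WT, and 2.37% and 1.55% in 3xAireKI. The median tuft-like cell had 7430.5 and 7505 UMIs in control, against 14030 and 14379.5 in the mature class. In AireKO, 0 of 279 and 0 of 398 thinned tuft-like cells had one, which allows shares of up to 1.08% and 0.754%, so the share in AireKO mature cells lay above that in tuft-like cells. Thymocyte-like cells, also a type that should lack Aire, had an Aire UMI in 61.1% of 18 and 44.4% of 36 thinned cells in control, 7.14% and 10.6% in WT, and 16.0% and 1.61% in 3xAireKI. In AireKO 0 of 23 and 0 of 26 had one (up to 13.0% and 11.5%). Droplets holding both an mTEC and a thymocyte were not told apart in this small class. The labels describe neither the deleted part of Aire nor the knock-in construct, and 3′ tags outside an altered part check nothing about it. Nor can the tags separate fewer transcripts from a changed 3′ end in 3xAireKI.

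**Figure D1:**
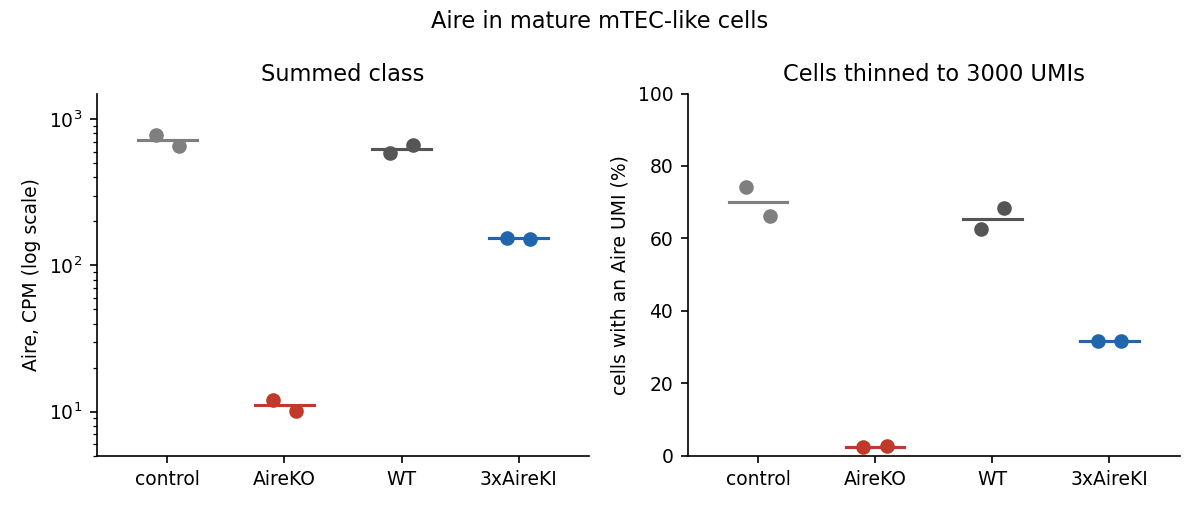
Aire in mature mTEC-like cells of each library (points) with the group mean (line), as CPM of the summed class on a log scale (left) and as the percentage of cells with an Aire UMI after thinning to 3000 UMIs (right). Both AireKO libraries lie far below control, and both 3xAireKI libraries lie between AireKO and WT.

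The comparison of AireKO with control asks which transcripts of mature mTEC-like cells depend on Aire. Among the largest falls, the serine protease gene Prss29 stood at 114 ± 9.17 CPM in control and the insulin gene Ins2 at 96.3 ± 10.1 CPM (n = 2), and neither had a single UMI in AireKO, at least 745-fold and 632-fold lower against a floor of 3 counts per library. Among the genes that rose were the protease gene Ctsh at 1252 ± 99.3 against 495 ± 25.3 CPM and the ICOS ligand gene Icosl at 259 ± 24.95 against 82.9 ± 9.85 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 8463 of 19839 genes changed at an adjusted p of 0.05, 2443 higher and 6020 lower. By library size, without the TMM factors (1.12 and 1.09 in control, 0.917 and 0.899 in AireKO), 8219 changed, 948 higher and 7271 lower. That scaling moves the median log2 fold change of all genes from −0.11 to −0.39, so small rises depend on the scaling. With single libraries of the fit left out the higher genes numbered 1395 (without control 1) to 4710 (without WT 2) and the lower 4070 (without AireKO 1) to 6530 (without WT 1).

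The 10 largest falls among named genes with at least 10 CPM in control all reached 0 UMIs in AireKO. They were Prss29 and Prss34 (serine proteases), Hba-x and Hbb-bt (globins), Ins2, Dcpp3, Sprr2i (a small proline-rich protein of cornified epithelia), Cytl1, Sbp and Defa21 (an intestinal defensin), with floors from at least 299-fold lower (Defa21) to at least 745-fold lower (Prss29). Hba-x, an embryonic globin gene, had 96.5 ± 23.2 CPM in control, which gives at least 633-fold. The largest rises were smaller. Ctla4, which encodes an inhibitory receptor best known from T cells, rose from 3.92 ± 0.477 to 43.3 ± 1.36 CPM (log2 fold change 3.46, SE 0.39; adjusted p = 0.000132, edgeR). Fam19a1 rose from 38.6 ± 8.07 to 250 ± 58.5 CPM, and the immunoglobulin kappa constant gene Igkc from 41.8 ± 5.49 to 201 ± 1.75 CPM. AY761185, Acot12, Ptgs2os2, Lum, Olfr1136, Plcd3 and AC132444.6 completed the 10, with log2 fold changes between 2.33 (Plcd3 and AC132444.6) and 3.39 (AY761185). Defa21, Dcpp3, AY761185, Sprr2i and the Prss genes have near-identical relatives whose reads the counting could split, so their levels are uncertain.

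Gene lists written before the data were examined were tested with fry. They were not tested with scaling by library size, so a small rise of a list in AireKO may depend on the scaling. Counts of members are at the threshold over all genes tested, and the count adjusted over the list alone follows where it differs. The p-values of fry depend to some degree on the order of the groups in the model, so all 24 orders were run, after this had been seen. In AireKO 26 of the 34 lists passed, 25 of them in each of the 24 orders. The keratin and junction list passed in 23 orders, the immature mTEC list in 13 and the B-cell list in 3, so these calls are not settled. Of the tissue genes known before as Aire-dependent, 27 of 32 measured members fell and 2 rose (28 and 2 adjusted over the list alone; fry adjusted p = 0.00171). Their median log2 fold change was −7.45, or −5.50 with the 12 members at 0 UMIs set to their bound. Camera, which compares a list with other genes, gave this list an adjusted p = 0.312 with an estimated correlation between its members. No list passed with camera in either comparison. Tff3, a trefoil peptide of the gut, stood at 1.06 ± 0.0863 against 114 ± 7.61 CPM (log2 fold change −6.73, SE 0.21; adjusted p = 1.44e-07, edgeR), Pyy, a gut hormone, at 0.604 ± 0.606 against 273 ± 65.4 CPM, and Sst, which encodes somatostatin, at 0.0293 against 119 ± 18.8 CPM. The list known before as Fezf2-dependent fell too, with 11 of 14 members lower and 1 higher (fry adjusted p = 0.00118; adjusted p = 0.312 with an estimated correlation). Pcp4 of that list fell from 260 ± 19.8 to 15.4 ± 1.21 CPM. The list known before as Aire-independent had 7 of 10 members lower and 1 higher, 8 and 1 adjusted over the list alone (fry adjusted p = 0.00896; adjusted p = 0.447 with an estimated correlation). Alb (5.67 ± 1.32 to 0.0430 ± 0.0608 CPM) was among these.

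Lists of specialised epithelial cells were tested within the class. Muscle genes had 9 of 11 members lower and 1 higher (fry adjusted p = 0.00740), such as the embryonic myosin gene Myh3, from 23.5 ± 13.1 to 0.145 ± 0.0388 CPM. Secretory airway genes had 7 of 8 lower (fry adjusted p = 0.00395). Scgb1a1 fell from 73.8 ± 23.8 to 0.248 ± 0.229 CPM and the mucin gene Muc5ac from 19.7 ± 4.22 to 0.203 ± 0.0441 CPM. Ionocyte genes had 6 of 9 lower and 1 higher, 7 and 1 adjusted over the list alone (fry adjusted p = 0.00162), with the transcription factor gene Foxi1 at 0 UMIs in AireKO, at least 45.2-fold lower. Corneocyte-like mTEC genes had 8 of 14 lower and 1 higher, 10 and 1 adjusted over the list alone (fry adjusted p = 0.00566). Krtdap fell from 63.2 ± 11.4 to 1.83 ± 0.269 CPM. Enterohepatic genes had 7 of 11 lower and 1 higher (fry adjusted p = 0.0124), among them the apolipoprotein gene Apoa1, from 198 ± 85.6 to 0.821 ± 0.248 CPM. Cluster 2 was kept out of the class through 1 enterohepatic marker, so this list was tested on cells partly chosen by it. That cluster held 8.37% and 12.1% of control and 7.87% and 6.88% of AireKO cells. With an estimated correlation the adjusted p was 0.329 for the muscle list, 0.328 for the secretory airway and ionocyte lists, 0.351 for the corneocyte list and 0.474 for the enterohepatic list. Microfold genes had 5 of 10 lower and 2 higher (fry adjusted p = 0.0104; adjusted p = 0.588 with an estimated correlation). The chemokine gene Ccl20 fell from 196 ± 56.0 to 19.7 ± 1.03 CPM and Gp2 from 14.97 ± 0.343 to 3.31 ± 1.77 CPM. Tuft genes had 5 of 14 lower and 1 higher (fry adjusted p = 0.0353, and 0.0793 with the batch as a block; adjusted p = 0.628 with an estimated correlation). Dclk1 fell from 17.7 ± 2.18 to 3.66 ± 1.46 CPM and Avil from 10.5 ± 1.48 to 2.51 ± 1.84 CPM. Neuroendocrine genes moved both ways, with 6 of 12 lower, 7 adjusted over the list alone, and 2 higher (fry adjusted p = 0.0353, and 0.118 with the block; adjusted p = 0.686 with an estimated correlation). Chga fell from 53.3 ± 8.80 to 23.1 ± 0.498 CPM, while Syt1 rose from 457 ± 5.61 to 887 ± 95.6 CPM and Insm1 from 142 ± 10.8 to 255 ± 23.9 CPM. Ciliated genes had 5 of 10 lower and 2 higher, which did not pass (fry adjusted p = 0.255). Tekt1 stood at 2.55 ± 0.639 CPM in control and 0.109 ± 0.0939 CPM in AireKO.

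Mature mTEC genes had 8 of 15 members higher and 1 lower, 9 and 1 adjusted over the list alone (median log2 fold change 0.44; fry adjusted p = 0.0104, and 0.0556 with the block; adjusted p = 0.329 with an estimated correlation). Cd52 rose from 1814 ± 200 to 4104 ± 73.9 CPM, the common cytokine receptor gamma chain gene Il2rg from 81.8 ± 1.36 to 148 ± 7.71 CPM and the costimulatory ligand gene Cd80 from 112 ± 16.0 to 168 ± 5.34 CPM, whereas the chemokine gene Ccl22 fell from 62.2 ± 23.2 to 13.6 ± 0.530 CPM. The class had been named by detection of the mature list, with Cd80, Cd52 and Il2rg among its markers. That list was therefore tested on cells chosen by it, as was any of its markers that stands in another list. Immature mTEC genes had 7 of 12 lower and 2 higher, and the list did not pass (fry adjusted p = 0.0757). Krt5 fell from 37.3 ± 7.70 to 11.3 ± 0.101 CPM. Cortical epithelial (cTEC) genes had 6 of 12 lower and 3 higher (fry adjusted p = 0.00619; adjusted p = 0.686 with an estimated correlation). Ctsl fell from 180 ± 3.41 to 44.6 ± 0.722 CPM. Ccl25, a chemokine gene of thymic epithelium, stood at 492 ± 39.7 CPM in AireKO against 917 ± 81.3 CPM in control, but its log2 fold change of −0.90 became 0.84 when no cluster was kept out of the class by its leading genes, and 1.00 over all kept cells.

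Antigen presentation genes had 12 of 24 members higher and 1 lower (fry adjusted p = 0.0104, and 0.0523 with the block; adjusted p = 0.349 with an estimated correlation), including Ctsh and Ciita, the MHC class II transactivator gene, which rose from 157 ± 1.39 to 317 ± 5.31 CPM. Costimulation genes had 6 of 12 higher and 1 lower (fry adjusted p = 0.00619; adjusted p = 0.312 with an estimated correlation). Icosl rose, and Tnfsf11, which encodes RANK ligand, fell from 3.54 ± 1.81 to 0.0801 ± 0.0525 CPM. The RANK, CD40 and NF-kB list had 14 of 22 higher and 1 lower, 14 and 2 adjusted over the list alone (fry adjusted p = 0.00619; adjusted p = 0.312 with an estimated correlation). The decoy receptor gene Tnfrsf11b rose from 144 ± 7.40 to 351 ± 41.6 CPM, Relb rose from 225 ± 10.9 to 392.2 ± 3.82 CPM and Bcl2a1b fell from 303 ± 54.1 to 75.1 ± 7.38 CPM. Apoptosis genes had 10 of 20 higher and 2 lower (fry adjusted p = 0.00154; adjusted p = 0.312 with an estimated correlation). The pro-apoptotic gene Bax rose from 290 ± 15.3 to 678 ± 54.0 CPM and Pmaip1 fell from 50.5 ± 2.08 to 20.5 ± 0.435 CPM. Interferon-stimulated genes had 18 of 25 lower and 0 higher (fry adjusted p = 0.00123; adjusted p = 0.312 with an estimated correlation). Rsad2 fell from 35.5 ± 5.98 to 1.27 ± 0.276 CPM and Ifit2 from 26.8 ± 3.17 to 1.54 ± 0.684 CPM. Chemokines and cytokines had 13 of 27 lower and 3 higher (fry adjusted p = 0.0142; adjusted p = 0.485 with an estimated correlation). Xcl1 fell from 45.3 ± 14.6 to 0.225 ± 0.0137 CPM. Keratin and junction genes had 9 of 24 lower and 4 higher (fry adjusted p = 0.0378; adjusted p = 0.864 with an estimated correlation). Krt19 fell from 58.3 ± 7.28 to 7.65 ± 0.783 CPM.

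Thymic transcription factor genes split, 8 of 31 higher and 8 lower, 8 and 9 adjusted over the list alone. The list did not pass (fry adjusted p = 0.812), and its median (−0.03) and mean (−0.95) lie below 0 while the test leans upwards. The intestinal factor gene Cdx2 had 0 UMIs in AireKO, at least 67.6-fold lower, and Irf8 rose from 294 ± 16.0 to 766 ± 50.2 CPM. Aire partners and elongation factors had 5 of 30 higher and 1 lower (fry adjusted p = 0.113). Chd6 rose from 172 ± 3.85 to 293 ± 1.13 CPM and the deacetylase gene Sirt1 from 496 ± 24.4 to 824 ± 93.1 CPM. Dissociation and stress genes had 3 of 20 lower and 2 higher, 3 and 1 adjusted over the list alone (fry adjusted p = 0.477). Hspb1 fell from 373 ± 0.838 to 151 ± 37.7 CPM and Jund rose from 572 ± 7.43 to 865 ± 84.1 CPM. Cycling genes had 3 of 15 lower and 1 higher (fry adjusted p = 0.170), with Mcm5 at 6.21 ± 0.491 in control and 1.77 ± 0.352 CPM in AireKO, and Cdk1 at 14.1 ± 0.254 and 38.2 ± 6.52 CPM. Of the 13 mitochondrially encoded genes 0 passed in edgeR, 0 had an unadjusted p under 0.05 and 0 passed in DESeq2 (fry adjusted p = 0.946); mt-Co1 was at 5152 ± 325 and 4702 ± 173 CPM in AireKO and control.

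Lists of cells outside the epithelium were tested in the same class. Fibroblast markers had 7 of 10 lower and 2 higher (fry adjusted p = 0.00334; adjusted p = 0.400 with an estimated correlation). The collagen gene Col1a1 fell from 25.1 ± 3.80 to 0.180 ± 0.171 CPM while Dcn rose from 50.9 ± 6.84 to 175 ± 8.32 CPM. Endothelial markers had 7 of 9 lower, 8 adjusted over the list alone (fry adjusted p = 4.81e-05; adjusted p = 0.329 with an estimated correlation), for example Plvap, from 21.0 ± 2.32 to 0.158 ± 0.141 CPM. Pericyte markers had 4 of 9 lower and 3 higher (fry adjusted p = 0.0342, and 0.0662 with the block; adjusted p = 0.768 with an estimated correlation). Acta2 fell from 60.0 ± 6.68 to 8.82 ± 3.03 CPM. Myeloid markers had 9 of 13 lower and 3 higher (fry adjusted p = 0.00694, and 0.0556 with the block; adjusted p = 0.447 with an estimated correlation). C1qb fell from 55.7 ± 7.58 to 9.02 ± 0.169 CPM. Clusters 0, 5 and 15, which held larger shares of AireKO than of control cells, were kept out of the class through 1 myeloid marker each. A lower myeloid list in AireKO may therefore be partly built in by that check. Thymocyte markers had 9 of 14 lower and 1 higher, 10 and 1 adjusted over the list alone (fry adjusted p = 0.00742; adjusted p = 0.362 with an estimated correlation). Cd3g fell from 13.1 ± 3.26 to 0.930 ± 0.342 CPM. Erythroid markers had 4 of 6 lower (fry adjusted p = 0.0202; adjusted p = 0.474 with an estimated correlation), Hbb-bs lying at 24.97 ± 9.90 CPM in control and 0.0293 ± 0.0414 CPM in AireKO. B-cell markers had 3 of 8 lower and 1 higher, which did not pass (fry adjusted p = 0.0902). Cd79a fell from 13.4 ± 1.67 to 0.602 ± 0.0604 CPM and Igkc was the 1 that rose.

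The 6020 genes that fell were also counted per cell. They were picked for falling in these same libraries, so a lower number of them in AireKO restates that choice. At 3000 UMIs a mature mTEC-like cell had UMIs of 127 ± 4.92 of these genes in control and 48.9 ± 0.938 in AireKO (n = 2), while the number of all genes per cell was 1422 ± 28.8 and 1380 ± 14.2. Without thinning the numbers of fallen genes were 342 and 333 in control, 138 and 109 in AireKO. Each difference separated the libraries completely, and 0.333 is the smallest p that an exact permutation test of 2 against 2 can give.

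**Figure D2:**
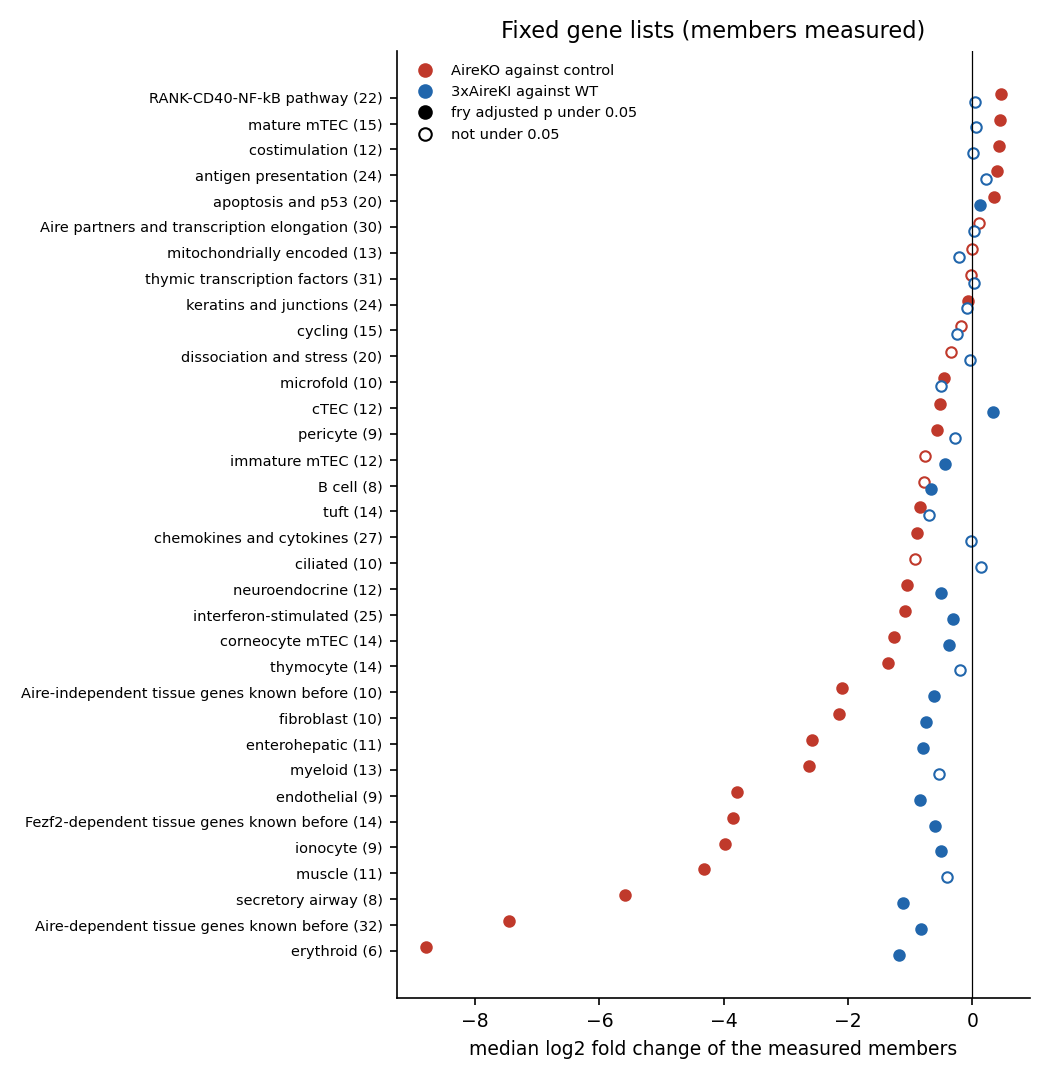
Median log2 fold change (x axis) of the measured members of each fixed gene list (y axis, number of members in parentheses) in mature mTEC-like cells, for AireKO against control (red) and 3xAireKI against WT (blue). Filled points have a fry adjusted p under 0.05; the erythroid, Aire-dependent and secretory airway lists lie furthest to the left in AireKO, and no list passes with an estimated correlation.

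The comparison of 3xAireKI with WT asks what the knock-in allele does to the same cells. Fewer genes changed and by less. Among the largest falls with at least 10 CPM in WT were the protease inhibitor gene Spink14, from 10.1 ± 3.44 to 0.984 ± 0.0243 CPM, and the uroplakin gene Upk3a, from 63.4 ± 3.09 to 10.4 ± 3.66 CPM. Among the largest rises, the homeobox gene Hoxb7 (chromosome 11, 96286623 to 96290162) rose from 1.57 ± 0.157 to 20.6 ± 1.76 CPM (log2 fold change 3.72, SE 0.26; adjusted p = 0.000567, edgeR) and Hoxb8 from 4.22 ± 1.95 to 36.6 ± 0.590 CPM. Of the 19839 genes tested, 461 changed, 153 higher and 308 lower. The count was 1069 with the batch number as a block (460 of the 461 among them), 56 without 3xAireKI 1 and 260 without 3xAireKI 2. When every library was given the same mix of clusters, an alternative chosen after seeing the data, 92 genes changed, 54 higher and 38 lower, of which 79 were among the 461. With leading genes taken against all other cells cluster 1 left the class and 175 genes changed. There the log2 fold changes of Crisp3, Scg2, Slc24a1, Plvap, Hbb-bt, Csn1s2a, Pcp4 and Ifit1bl1 turned positive, as did those of Ctsl and Gng13 over all kept cells.

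The other falls among the 10 were Shisa8 (15.007 ± 0.648 to 1.96 ± 0.166 CPM), the estrogen sulfotransferase gene Sult1e1 (17.9 ± 4.10 to 2.60 ± 0.871 CPM), Hbb-bs (29.1 ± 13.4 to 4.35 ± 1.37 CPM), Crisp3 (15.4 ± 4.76 to 2.25 ± 0.244 CPM), the secretogranin gene Scg2 (19.5 ± 3.88 to 2.89 ± 1.18 CPM), Pcsk1n (10.7 ± 3.28 to 1.71 ± 0.853 CPM), the pancreatic gene Reg2 (12.9 ± 5.05 to 2.16 ± 0.524 CPM) and Slc24a1 (27.3 ± 5.08 to 4.64 ± 0.746 CPM). Among the rises, the serotonergic transcription factor gene Fev (chromosome 1, 74881509 to 74885419) went from 3.87 ± 1.16 to 35.0 ± 7.42 CPM and its neighbour Cryba2, a lens crystallin gene (74889934 to 74893143), from 80.5 ± 8.42 to 369 ± 96.6 CPM. Gchfr, which encodes a regulator of tetrahydrobiopterin synthesis, rose from 44.0 ± 0.851 to 158 ± 9.25 CPM, Kazald1 from 24.0 ± 7.22 to 86.9 ± 15.4 CPM, Neurod2 from 6.20 ± 2.51 to 22.8 ± 10.3 CPM, Ctsj from 0.479 ± 0.528 to 10.5 ± 6.92 CPM and the long non-coding RNA AL589670.1 (chromosome 15, 79015329 to 79025782) from 10.8 ± 0.877 to 89.4 ± 9.60 CPM. Hoxb5os, which overlaps Hoxb5 and is uncertain for that reason, rose from 1.5 ± 0.634 to 18.1 ± 2.53 CPM.

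Of the Aire-dependent list 6 of 32 members fell, 16 adjusted over the list alone (median log2 fold change −0.83; fry adjusted p = 0.0387; adjusted p = 0.175 with an estimated correlation). Tff3 fell from 209 ± 32.7 to 99.3 ± 8.61 CPM, the calprotectin gene S100a8 from 1191 ± 72.7 to 319 ± 52.8 CPM, Fabp9 from 297 ± 51.7 to 99.3 ± 0.771 CPM and the casein gene Csn1s2a from 59.5 ± 22.9 to 22.6 ± 5.26 CPM. The Aire-independent list had 2 of 10 members lower, among them Crp (10.2 ± 2.49 to 4.92 ± 0.193 CPM), and 5 lower adjusted over the list alone (fry adjusted p = 0.0387; adjusted p = 0.175 with an estimated correlation). The Fezf2-dependent list had 2 of 14 lower, Pcp4 (266 ± 15.3 to 134 ± 23.7 CPM) and Apob (14.4 ± 0.844 to 6.40 ± 1.46 CPM), or 4 lower and 1 higher adjusted over the list alone (fry adjusted p = 0.0387, and 0.0909 with the block; adjusted p = 0.175 with an estimated correlation). Fezf2 itself, the other regulator of tissue genes in mTECs, rose from 552 ± 102 to 1005 ± 83.1 CPM (log2 fold change 0.86, SE 0.15; adjusted p = 0.0211, edgeR).

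Corneocyte-like mTEC genes had 2 of 14 lower, 6 adjusted over the list alone (fry adjusted p = 0.0398; adjusted p = 0.175 with an estimated correlation), among them Krtdap, from 62.7 ± 0.0422 to 17.7 ± 2.40 CPM. Secretory airway genes had 2 of 8 lower, 4 adjusted over the list alone (fry adjusted p = 0.0396, and 0.0564 with the block). Scgb1a1 fell from 100.0 ± 3.94 to 25.7 ± 8.28 CPM. Ionocyte genes had 0 of 9 past the edgeR test, 3 lower at an unadjusted p under 0.05 and 0 in DESeq2 (fry adjusted p = 0.0396, and 0.0674 with the block). Neuroendocrine genes had 1 of 12 lower, Chga (52.9 ± 8.01 to 25.8 ± 2.61 CPM; 2 adjusted over the list alone; fry adjusted p = 0.0398, and 0.155 with the block). Immature mTEC genes had 0 of 12 past the edgeR test, 6 lower adjusted over the list alone and at an unadjusted p under 0.05, and 3 lower in DESeq2 (fry adjusted p = 0.0398, and 0.131 with the block); Ccl21a, the highest of them, was at 780 ± 89.3 against 1472 ± 365 CPM in WT (adjusted p = 0.106, edgeR, and 0.00682 with the block). With an estimated correlation the adjusted p was 0.175 for the secretory airway and immature lists and 0.229 for the ionocyte and neuroendocrine lists. Cortical genes had 2 of 12 higher and 1 lower, 6 and 1 adjusted over the list alone (fry adjusted p = 0.0387, and 0.112 with the block; adjusted p = 0.175 with an estimated correlation). Tbata rose from 1630 ± 318 to 2909 ± 35.8 CPM and Ccl25 from 1275 ± 75.9 to 2172 ± 18.6 CPM, and Ctsl fell from 351 ± 8.16 to 184 ± 39.996 CPM. Enterohepatic genes had 0 of 11 past the edgeR test, 2 lower adjusted over the list alone, 4 lower at an unadjusted p under 0.05 and 2 lower in DESeq2 (fry adjusted p = 0.0407, and 0.0537 with the block; adjusted p = 0.175 with an estimated correlation). Microfold genes did not pass (fry adjusted p = 0.0747) but did with the block (fry adjusted p = 0.0387). Of the 34 lists 16 passed in 3xAireKI, 14 of them in each of the 24 group orders, the immature mTEC list in 19 and the enterohepatic list in 12, so the last pair is not settled.

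Interferon-stimulated genes had 4 of 25 lower and 1 higher, 11 and 1 adjusted over the list alone (fry adjusted p = 0.0396, and 0.112 with the block; adjusted p = 0.175 with an estimated correlation). Ifit3 fell from 27.5 ± 0.794 to 7.97 ± 1.84 CPM, Rsad2 from 18.04 ± 3.21 to 6.28 ± 1.77 CPM and Ifit1bl1 from 7.35 ± 1.32 to 0.626 ± 0.680 CPM, and Oasl2 rose from 165 ± 20.6 to 302 ± 50.6 CPM. Apoptosis genes had 1 of 20 higher, Bbc3 (37.4 ± 0.140 to 56.9 ± 1.93 CPM; fry adjusted p = 0.0387, and 0.0970 with the block; adjusted p = 0.175 with an estimated correlation). Erythroid markers had 2 of 6 lower, Hbb-bs and Hbb-bt (34.6 ± 5.58 to 10.5 ± 1.74 CPM), 4 adjusted over the list alone. Fibroblast markers had 1 of 10 lower, Col1a1 (24.0 ± 6.82 to 7.51 ± 2.64 CPM), 3 adjusted over the list alone. Endothelial markers had 1 of 9 lower, Plvap (18.5 ± 3.66 to 8.15 ± 0.104 CPM), and B-cell markers 0 of 8 in edgeR, 3 lower adjusted over the list alone and at an unadjusted p under 0.05, and 2 lower in DESeq2. The fry adjusted p was 0.0396 for the erythroid list and 0.0387 for the fibroblast, endothelial and B-cell lists, and with an estimated correlation the adjusted p of these 4 was 0.175. With the block it was 0.0309 for the erythroid list, 0.0505 for the fibroblast list, 0.112 for the endothelial list and 0.0712 for the B-cell list.

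The other 18 lists did not pass in 3xAireKI, with fry adjusted p from 0.0747 (microfold) to 0.920 (keratins and junctions). Single members of these lists that changed were Gng13 of the tuft list (42.3 ± 12.6 to 16.7 ± 4.08 CPM), Myh3 of the muscle list (17.7 ± 0.410 to 4.11 ± 0.821 CPM), Stmn1 of the cycling list (65.6 ± 9.36 to 40.7 ± 2.62 CPM), and Lyz2 (979 ± 130 to 447 ± 34.2 CPM) and C1qb (69.6 ± 14.8 to 39.7 ± 1.25 CPM) of the myeloid list. The immunoproteasome gene Psmb9 rose from 271 ± 41.3 to 434 ± 8.66 CPM and Traf2, of the RANK, CD40 and NF-kB list, from 45.6 ± 0.949 to 70.1 ± 3.64 CPM. With the same mix of clusters 0 of the 34 lists passed in 3xAireKI by fry, the lowest adjusted p being 0.0542 (B-cell markers).

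The effects of the knock-in and of the loss of Aire were then set side by side. The comparisons share no libraries. Across the 19839 genes their log2 fold changes correlated (Pearson 0.406, Spearman 0.429; genes are not independent replicates). For the 8836 genes with a mean of at least 10 CPM these were 0.469 and 0.291. Of the 308 genes lower in 3xAireKI, 268 were also lower in AireKO, where 93.5 would be shared by chance, and 42 of the 153 higher genes were also higher, where 18.8 would be. Without 3xAireKI 1 the shared genes numbered 27 lower and 7 higher, with the same mix of clusters 27 and 13, and with the block 647 and 110. The 6020 genes that fell in AireKO had a median log2 fold change of −0.52 in 3xAireKI against WT, and the 2443 that rose a median of 0.087. Both sets passed (fry adjusted p = 0.00600 for each, adjusted over the pair of sets), in all 24 group orders. With the same mix of clusters the fallen set had a median of −0.10 and the risen set 0.044, and neither passed (fry adjusted p = 0.0656 for each). Without 3xAireKI 1 the fallen set no longer passed (median −0.40, fry adjusted p = 0.0541), and without WT 2 its median was −0.30 (fry adjusted p = 0.0495). Per thinned cell, 96.8 ± 0.321 of the fallen genes were seen in 3xAireKI and 120 ± 2.46 in WT (235 and 200 against 309 and 241 without thinning; exact permutation p = 0.333, the smallest possible).

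**Figure D3:**
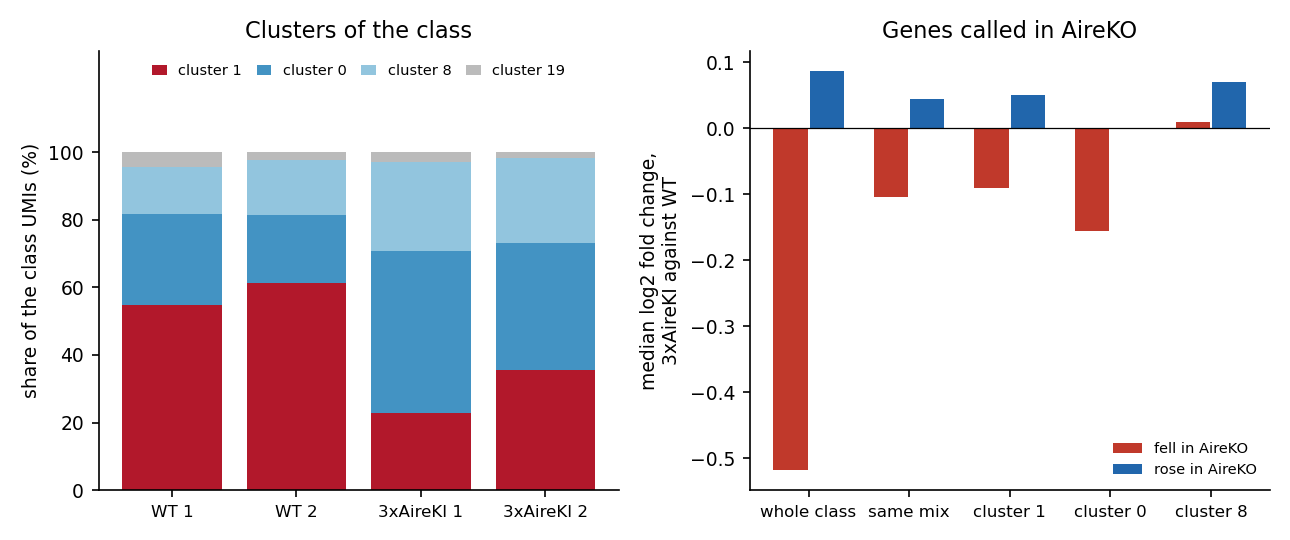
Left, percentage of the UMIs of the mature mTEC-like class that came from each cluster in the 4 libraries of the knock-in experiment. Right, median log2 fold change in 3xAireKI against WT of the genes that fell (red) or rose (blue) in AireKO, for the whole class, for the class with the same mix of clusters in every library, and within clusters, which test fewer genes; the median of the fallen genes goes from −0.52 to −0.10 with the same mix.

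In a test of the difference itself, 4315 genes responded differently to the knock-in and to the loss of Aire, 3393 with the higher response in 3xAireKI and 922 with the lower. By library size alone the numbers were 4539, 4121 and 418. The count was 2446 without AireKO 1 and 2639 without AireKO 2. Genes called in both with opposite signs numbered 52. The difference passed in 52 of them, which such calls in the same fit make nearly certain. Of these, 43 were higher in 3xAireKI and lower in AireKO, among them Hoxb7, Hoxb8, Fev, Cryba2, Gchfr and Neurod2, and 9 were lower in 3xAireKI and higher in AireKO. By chance 46.4 and 37.9 would be shared, so the 43 did not exceed chance and the 9 lay below it. Fisher's exact test gave p = 0.597 and 7.14e-09, though genes are not independent. The numbers were 23 and 2 with the same mix, and 77 and 31 with the block, where the numbers by chance were not computed.

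**Figure D4:**
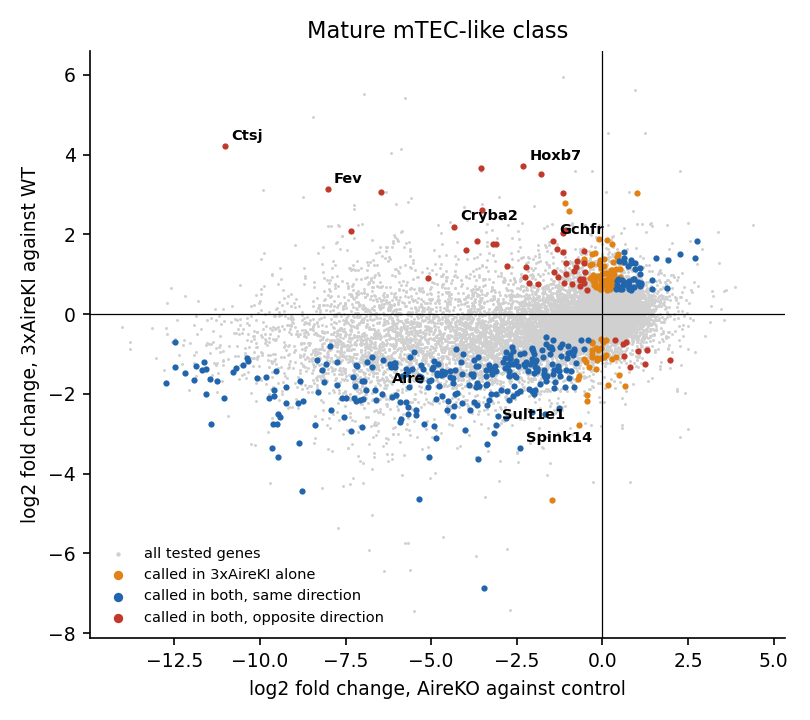
Log2 fold change in AireKO against control (x axis) and in 3xAireKI against WT (y axis) for each of the 19839 genes tested in mature mTEC-like cells; colours mark genes called in 3xAireKI alone, or in both with the same or the opposite direction. Of the 461 genes called in 3xAireKI, 310 were called in AireKO in the same direction (268 lower and 42 higher) and 52 in the opposite one.

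Fewer genes changed in the other classes. In AireKO 1132 of 11529 genes tested changed in corneocyte-like cells, 482 of 12505 in tuft-like cells, 162 of 13802 in immature mTEC-like cells (270 with the block), 79 of 9296 in neuroendocrine-like cells (196 with the block), 59 of 11958 in cycling cells (214 with the block), 48 of 8434 in microfold-like cells and 3 of 6560 in cortical-like cells (25 with the block). In 3xAireKI the counts were 17 in tuft-like cells (28 with the block), 5 in corneocyte-like cells (28), 4 in immature mTEC-like cells (15) and 1 in cycling cells, Aire (35). The clusters behind a class differed between groups here too. Cluster 9 held 73.3% and 73.6% of tuft-like cells in control and 33.0% and 51.9% in AireKO, and cluster 3 held 71.5% and 61.0% of immature cells in control and 53.2% and 38.0% in AireKO. These classes were not tested with the same mix. Fewer cells and UMIs stood behind these sums, so the counts do not rank the classes by their response.

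The shares of the classes among kept cells differed between the groups. Immature mTEC-like cells made up 7.60% ± 2.67 of AireKO and 23.1% ± 0.335 of control cells (SD, n = 2), tuft-like cells 5.71% ± 1.45 and 8.24% ± 0.200, microfold-like cells 0.974% ± 0.0008 and 3.06% ± 0.450, and neuroendocrine-like cells 0.896% ± 0.278 and 2.74% ± 0.0609. Ciliated-like cells were 1 of 5950 and 0 of 6573 cells in AireKO (the latter allows a share of up to 0.0456%) against 64 of 4443 and 38 of 4198 in control. Cycling cells were at 2.93% ± 1.44 and 2.98% ± 1.58, a difference within the spread. Mature mTEC-like cells were 34.9% ± 2.16 in AireKO and 29.2% ± 3.53 in control, but this share is not settled. A check of leading genes, set after the data were seen, kept 37.6% and 37.0% of AireKO cells and 13.9% and 16.7% of control cells out of the class, and the difference of 5.75 percentage points ranged from 1.20 to 27.8 over the alternatives. With leading genes taken against all other cells the immature difference was −3.51 instead of −15.5 points. In 3xAireKI mature mTEC-like cells made up 30.6% ± 2.09 and in WT 23.5% ± 1.25, a difference of 7.11 points that ranged from 4.56 to 11.5 over the alternatives and is not settled either. Cycling cells made up 3.31% ± 0.0332 and 4.98% ± 0.162, and immature cells 47.1% ± 6.03 and 48.5% ± 7.14. No share can pass here: the exact permutation test of 2 against 2 libraries gives no p under 0.333. Shares also depend on the sort and on the UMI threshold of each library.

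**Figure D5:**
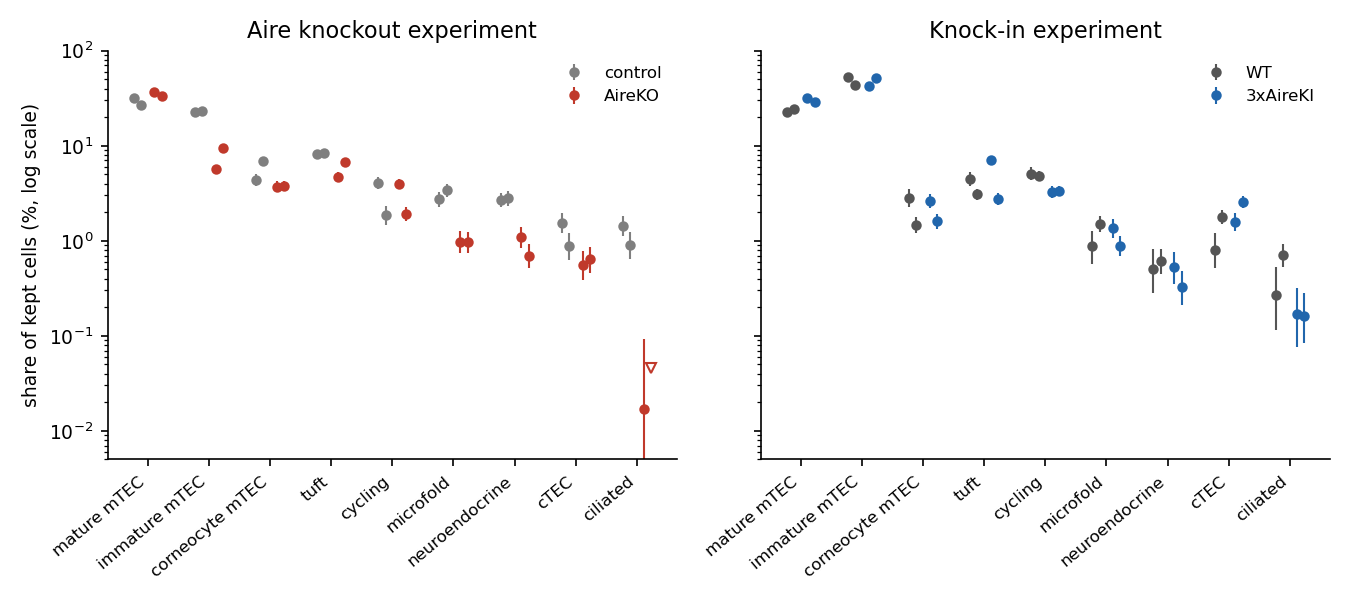
Percentage of kept cells of each library (log scale, points with exact 95% binomial intervals, which cover counting error only) in each named class, for the knockout experiment (left) and the knock-in experiment (right). An open triangle marks a count of 0 at the limit it allows; immature, microfold, neuroendocrine and ciliated-like shares are lower in both AireKO libraries than in both control libraries.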

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

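The tests of the difference between the comparisons were planned, whereas the tests of linked DNA, of other cells, of neighbouring genes and of the Hox family were chosen only after the results were seen.

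Each gene here was picked up because its response to the knock-in differed from its response to the loss of Aire in edgeR's test of that difference with Benjamini-Hochberg adjustment, and because it was called in both comparisons with opposite directions. The adjusted p of the difference restates that choice and is no separate support. For genes with 0 or 1 UMI in AireKO (Ctsj, Fev and Hoxb8) the fitted size depends on the prior count and is no bound. On the log2 scale Hoxb7 differed by 6.04 (adjusted p = 2.53e-05), with 3.72 in 3xAireKI and −2.31 in AireKO. Hoxb8 differed by 9.54 and Hoxb5os by 5.31 (adjusted p = 0.000257 and 0.000396). The neighbours Fev and Cryba2 differed by 11.16 and 6.52 (adjusted p = 6.38e-05 and 2.19e-05). Ctsj differed by 15.25 (adjusted p = 0.000455), with UMIs of 117 and 293 in 3xAireKI, 1 and 14 in WT, 193 and 365 in control, and 0 in AireKO. Neurod2 differed by 5.52 (adjusted p = 0.000659) and AL589670.1 by 4.20 (adjusted p = 1.78e-05).

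Gchfr differed by 3.29 (adjusted p = 1.16e-05), with 1.85 in 3xAireKI and −1.44 in AireKO. Ccl25 differed by 1.67 (adjusted p = 0.000367), though its direction in AireKO turned with the choice of clusters. Oasl2 differed by 1.52 (adjusted p = 0.00122), higher in 3xAireKI and lower in AireKO. The tuft gene Gng13 differed by −2.12 (adjusted p = 0.00232), lower in 3xAireKI (−1.33) and higher in AireKO (0.79).

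The first pattern weighed is the rise of 8 Hoxb and Hoxc genes in 3xAireKI, of which 7 were called lower in AireKO. Aire lies on chromosome 10 and these genes on chromosomes 11 and 15, so 0 of the 8 lie within 5000000 bp of Aire. Linked DNA carried with the knock-in therefore does not include them, but its effects on distant genes were not tested. Of the 210 genes tested in that window 3 were called, Aire among them (1.43%, against 2.34% elsewhere), which decides nothing about such effects. Admixture of corneocyte-like, cycling, immature or tuft-like cells is argued against, since the class with the highest level would have to supply a median of 84.2% of the class UMIs. The smaller classes were not weighed. Within clusters 0, 1 and 8 the medians of those tested were also above 0 on the log2 scale (2.74, 1.86 and 1.97), though none passed (fry adjusted p = 0.0865, 0.0881 and 0.0865 over 12 tests) and the genes were picked on the same libraries. Neighbouring genes may change together, as 49 of the 153 higher genes had another within 100000 bp, against a mean of 5.69 and at most 20 over 10000 shuffles (permutation p = 0.0001, the smallest they can give). The 49 include adjacent Hoxb genes that prompted the test, and no count without them was made. Of the 308 lower genes 61 had another lower one, against a mean of 19.9 and at most 45. Whether the whole Hox family rises stays open (9 of 37 higher, fry adjusted p = 0.0552 over 228 families; adjusted p = 0.721 with an estimated correlation), as does an effect of the altered Aire allele, which these samples name but do not test apart from other differences between the mice.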

How the results depend on the processing

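The 2 versions of the check of leading genes, the subtraction of free RNA, the same mix of clusters and the orders of the groups were chosen only after the results were seen; all other alternatives were planned. The cause was not tested unless named. The count of 8463 genes in AireKO stayed within 1.5 times under each alternative, including each library of the joint fit left out (6036 to 10896) and the replicate block (9037). Its 2443 higher genes were 948 by library size, 1395 without control 1, 1415 without control 2 and 4710 without WT 2. With the same mix, cluster 1 of the knockout experiment had a weight of 34.7% but only 59 and 41 cells in AireKO 1 and AireKO 2. Within single clusters of the class, which test fewer genes, 681 (cluster 6) to 1898 (cluster 4) genes were called in AireKO. The count of 461 in 3xAireKI was 868 with DESeq2, 1438 without the filter, 1069 with the replicate block, 190 with the 4 libraries alone, 84 over all kept cells, 175 with leading genes taken against all other cells and 92 with the same mix, and it ran from 56 (without 3xAireKI 1) to 479 with each library left out. The 4315 genes of the difference ran from 2446 to 5012 with each library left out. Of the named genes, 1556 of 1577 values in AireKO and 746 of 1007 in 3xAireKI kept direction and call, 16 and 246 lost the call with their direction, 0 and 5 gained it, and 5 and 10 reversed. The block changed the call of 1 named gene, Ccl21a.

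The median of the fallen genes in 3xAireKI (−0.52) was −0.10 with the same mix (fry adjusted p = 0.0656), −0.28 over all kept cells and −0.81 for the 200 largest falls, and ran from −0.66 to −0.30 with each library left out; without 3xAireKI 1 it was −0.40 (fry adjusted p = 0.0541). That of the risen genes (0.087) was 0.044 with the same mix (fry adjusted p = 0.0656) and ran from 0.0857 to 0.1536 with each library left out. The genes called in both comparisons, 268 lower and 42 higher, were 27 and 7 without 3xAireKI 1, 27 and 13 with the same mix, and 647 and 110 with the replicate block. Of the fixed lists, 26 passed in AireKO and 16 in 3xAireKI. With an estimated correlation 0 passed in either. In 3xAireKI 5 passed with the replicate block, 0 over all kept cells, 8 with no check of leading genes and 0 with the same mix. The order of the groups in the model moved the numbers from 25 to 28 and from 14 to 16.

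The mature share in AireKO differed by 1.20 points at 2 times the UMI threshold, 21.1 with genotype-called genes in the clustering, 16.9 with leading genes taken against all other cells and 27.8 with no check. The immature share differed by −11.0, −11.6 and −3.51 under the first 3 of these. In 3xAireKI the mature share differed by 4.56 at 2 times the threshold, 5.27 at a mitochondrial limit of 5% and 11.5 with leading genes against all other cells. Thinned to 1500 UMIs, cells with an Aire UMI differed by −54.1 points in AireKO and −30.0 in 3xAireKI, and fallen genes per cell by −49.8 and −14.8, as fewer UMIs are seen. The summed counts of the other classes, 1965 in AireKO and 27 in 3xAireKI, were 4967 and 816 without the filter, which tests more genes, and 106 in 3xAireKI with the replicate block.

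Reversed log2 values in AireKO were those of Ccl25 (0.30 with leading genes against all other cells, 0.84 with no check, 0.37 with the same mix, 1.00 over all kept cells) and mt-Co1 (−0.15 by library size). In 3xAireKI Crisp3 (1.08), Scg2 (1.32), Slc24a1 (1.66), Plvap (0.76), Hbb-bt (0.62), Csn1s2a (0.26), Pcp4 (0.12) and Ifit1bl1 (0.15) reversed with leading genes against all other cells, where cluster 1 leaves the class, and Ctsl (0.13) and Gng13 (0.27) over all kept cells. Whether depth limits the calls in the other classes was not tested, and genes near 0 UMIs rest on few counts.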

Other observations

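The tests of the UMI threshold and of the medians within clusters were planned before their results were seen. The subtraction of free RNA was added after the first results were seen and before its own. The share of free RNA in other classes, the test with the same mix of clusters and the test of dilution, all genes named in the first 2 paragraphs, and the gene families were chosen only after the results were seen.

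Genes outside the mature class also moved in AireKO (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in each class). No class here was tested with the same mix of clusters. Some of the genes called were also called in mature cells in the same direction. In corneocyte-like cells these were 822 of 1132, in tuft-like cells 329 of 482 and in immature cells 87 of 162. In neuroendocrine-like cells they were 61 of 79 and in microfold-like cells 42 of 48. Tuft-like cluster 13 scored 0.529 for the tuft list and 0.525 for the mature list. Changes of a class were not told apart from mature cells within it. In immature mTEC-like cells the chitinase-like genes Chil4 and Chil3 were at 563 and 365 CPM, against 22.5 and 16.2 CPM in control (log2 fold changes 4.64 and 4.49; adjusted p = 0.000520 and 0.000539). Laptm5, a lysosomal membrane gene best known from blood cells, was at 110 against 13.8 CPM there, and Sema3a, which encodes a guidance cue, at 9.90 against 46.3 CPM. In corneocyte-like cells Batf3, a transcription factor gene of dendritic cells, rose by a log2 of 3.75 (adjusted p = 7.72e-05), and the calcium-binding protein gene S100g was at 2162 against 355 CPM. S100g was also higher in tuft-like cells (236 against 24.1 CPM) and in neuroendocrine-like cells (1253 against 338 CPM). Irf8, which rose in mature cells, was higher in microfold-like (211 against 49.95 CPM), corneocyte-like (607 against 219 CPM), tuft-like (85.2 against 40.02 CPM) and neuroendocrine-like cells (170 against 75.9 CPM). In neuroendocrine-like cells Tff3 was at 10.1 against 792 CPM and Reg3g, which encodes an antimicrobial lectin, at 336 against 4039 CPM. In tuft-like cells the prostaglandin D synthase gene Ptgds was at 3.16 against 57.2 CPM. Cortical-like cells, few in number, held the nitric oxide synthase gene Nos2 at 116 against 2.49 CPM (adjusted p = 0.00128).

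In 3xAireKI, Aire was lower in immature mTEC-like cells (3.31 against 20.8 CPM; the free RNA measured would bring 0.187 of 3.15 CPM there and 5.30 of 19.9 CPM in WT before TMM scaling) and in cycling cells (92.3 against 519 CPM; edgeR adjusted p = 9.31e-07). Of the genes the text names in the mature class, S100a8 and Fabp9 also passed in immature cells, but there free RNA would bring 12.03 CPM against a level of 14.1 and 8.67 CPM against 8.09 in WT, so these are not read as expression in that class. Krtdap and Ifit3 were lower in tuft-like cells (4.57 against 79.1 and 8.05 against 53.7 CPM), where free RNA would bring 8.71 of 74.3 and 7.11 of 50.9 CPM in WT, and Gchfr was higher in corneocyte-like cells (149 against 43.7 CPM). Among 228 gene families defined by shared symbols, all 13 pregnancy-specific glycoprotein (Psg) genes fell in AireKO, as did 11 of 12 small proline-rich (Sprr), 10 of 11 aquaporin (Aqp) and 20 of 37 Hox genes. Their fry adjusted p ran from 0.000933 (Aqp) to 0.0147 (Sprr), but with an estimated correlation their adjusted p was 0.335, and 0.479 for Sprr. Members of the Psg and Sprr families share sequence, so the counting could split their reads. Ribosomal protein families went the other way in AireKO, with 33 of 54 Rpl genes higher and 1 lower, and 25 of 44 Rps genes higher and 4 lower. Their fry adjusted p was 0.0178 and 0.0416, and 0.423 and 0.484 with an estimated correlation.

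The second pattern is that genes fallen in AireKO lay lower in 3xAireKI than in WT. More free RNA in WT 1 is argued against, since the median was −0.53 after its subtraction and −0.52 before. A different mix of clusters may be part of the cause, as the median was −0.10 with the same mix in every library. Whether it is the whole cause cannot be told apart: within the 3 largest clusters, which test fewer genes, the medians were −0.16, −0.091 and 0.010 (fry adjusted p = 0.0881, 0.304 and 0.646 over 12 tests), where the same genes had −0.33, −0.49 and −0.32 in the whole class. The mix may itself follow from the altered Aire allele, since the clusters differ in genes that were not left out of the clustering, and balancing could then remove a true effect.

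The third pattern is the lower share of immature mTEC-like cells in AireKO. Whether the UMI threshold removed small cells cannot be told. Among cells with at least 2 times that threshold the difference was −11.0 percentage points, against −15.5 over all. A higher threshold sees no cell that the first had already removed. The naming of clusters stays open, as the difference was −3.51 points when leading genes were taken against all other cells. Dilution by more mature cells cannot be told apart for this reason. The highest ratio of AireKO to control libraries was 0.416 for immature cells and the lowest for tuft-like and corneocyte-like cells was 0.541, but with leading genes against all other cells the immature ratios ran from 0.294 to 0.905, and with genotype-called genes in the clustering from 0.4095 to 0.5545, and overlapped them. Microfold-like (0.288 to 0.355) and neuroendocrine-like cells (0.251 to 0.4045) had ratios as low as the immature ones. A biological difference in immature cells without Aire was not tested apart from the sort.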
